A study of Mus musculus with 6 samples.

How the data were processed

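The series holds 6 RNA sequencing libraries from distal, tumour-bearing colon of male C57BL/6 mice, 3 labelled Otud1-/- and 3 wild type. Mice entered at 6 weeks of age, received azoxymethane on day 0 and then 3 cycles of dextran sulphate sodium (1.5%, 4 days) with 14 days of water, and colon was taken on day 81. The label of each sample gives an age of 18 weeks. Total RNA was extracted with Trizol and made into libraries with an Illumina protocol, per the labels' protocols. The genome build was mm10, per the submitters' processing notes. The aligner, the counting tool, the strand setting and the annotation release are not given in the sources used here.

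The deposited table holds one signal value per gene and library for 21851 Ensembl gene IDs, and the authors had divided each library's gene reads by a scaling factor. This was read from the values: in each library, every value is a whole multiple of the smallest positive value (100% of values within a tolerance of 1e-06 of a whole multiple). Whole reads were therefore recovered. Median-of-ratios factors recomputed from these reads equalled the deposited scaling. No gene in the table has fewer than 10 reads over the 6 libraries. The recovered reads sum to 22112459, 23827281 and 22219403 in the libraries labelled Otud1-/- and to 21275960, 20802432 and 14826643 in the wild-type libraries. A count of 0 allows up to 3 reads, which is a normalised value of 3.98 in the shallowest library (wild type replicate 3) and 2.6 in the deepest (Otud1-/- replicate 2). Such floors cover counting error only. Gene symbols and positions were taken from GENCODE release M21 by Ensembl ID without its version; 21797 IDs matched a symbol, 54 did not, and 88.3% matched with the same version, so the release used for counting differed from M21.

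The test had been fixed before the data were examined for a table of counts or of CPM, TPM, RPKM or FPKM values. The table held counts divided by scaling factors, so the test fixed for normalised values was used: limma-trend with robust variance estimates (limma 3.58.1, R 4.3.3) on log2(value + 1). Genes with a value of at least 1 in at least 3 libraries were kept (21796 genes), p-values were adjusted by the Benjamini-Hochberg method, and the threshold was 0.05. Fold changes are on the log2(value + 1) scale, as libraries labelled Otud1-/- minus wild type, and understate the change of low genes. Group values are means of normalised read counts ± SD. Count tests on the recovered reads were added after the file was seen: edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 (Wald test, adjusted p left missing where independent filtering or outlier detection gave none).

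Before the data were examined, 46 gene lists were drawn up for pathways linked to OTUD1 or to colon tumours, for the cell types of the distal colon, for other tissues and for RNA quality. Each list with at least 5 measured members was tested with camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 46 lists. Camera with an estimated correlation and fry were the alternatives. Fry tests whether a list's genes move, on balance, in one direction and does not set them against other genes. Beside each list, the members past the threshold are also counted after adjustment over the list alone.

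Genes were named by a rule fixed at the same time: Otud1, then genes past the threshold whose groups do not overlap and whose mean lies above the lowest quartile of the genes tested, with predicted and clone names and immunoglobulin and T cell receptor segments left out. Since no gene passed in limma, the 5 with the smallest p in each direction among genes meeting the other conditions, non-overlap included, were named and said not to pass. Up to 4 members with the smallest p were named per list. Gm16867, Gm21451, Slc25a37, Loxl2, Nnt and Cyp2c55 were also looked at after their values were seen.

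The procedure was tested on simulated data with the real genes' means, dispersions and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. Changed genes, and those of the simulated list below, were drawn only from genes above a floor of mean value. The recovery of low genes was therefore not measured. For this comparison of 3 with 3 libraries, limma-trend recovered 54% of genes changed 2-fold and 94% of genes changed 4-fold, with 15 false calls among 166. DESeq2 recovered 71% and 99%, with 56 false calls among 234. A simulated list of 30 genes changed 1.5-fold was called with the preset and with the estimated correlation, and 0 of 46 random lists were called; the simulated genes varied independently of each other, unlike the members of real lists.

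Alternatives fixed beforehand were quantile normalization, limma without trend and robust fitting, other filters (any value above 0, or at least 5 in 3 libraries), pseudocounts of 0.1 and 0.01, sample weights, the replicate number as a block, a fold-change threshold, and leaving out each library in turn. The labels do not say whether each library came from a separate mouse, so p-values measure the spread between these samples. An exact permutation test of a single value in 3 against 3 libraries cannot go below p = 0.1.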

Results

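Gene expression was measured by RNA sequencing in distal colon carrying tumours induced with azoxymethane, a carcinogen, and dextran sulphate sodium, an irritant that causes colitis. The comparison asks how the tumour-bearing colon of mice labelled as lacking Otud1, which encodes a deubiquitinase of the OTU family, differs from that of wild-type mice. There were 3 libraries per genotype, with 14826643 to 23827281 recovered reads each. Log2 expression correlated at r = 0.973 to 0.981 across genes between libraries of the same group and at 0.97 to 0.979 between libraries of different groups; genes are not independent replicates.

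The targeted gene was not lower in the libraries labelled Otud1-/-. Otud1 (ENSMUSG00000043415.5, mm10 chromosome 2, 19657752 to 19660583, plus strand, 1 exon) averaged 105 ± 12.1 normalised reads (SD, n = 3) in the libraries labelled Otud1-/- and 51.5 ± 15.4 (SD, n = 3) in the wild-type libraries. Its recovered reads were 99, 136 and 117 in the libraries labelled Otud1-/- and 44, 69 and 31 in the wild-type libraries. The log2 difference of 1.05 (SE 0.26) did not pass the threshold in limma (adjusted p = 0.456 over all genes). For this gene, fixed beforehand, the unadjusted limma p was 0.00338. On the recovered reads its adjusted p was 0.06 in DESeq2 and 0.458 in edgeR, also short of the threshold. A value per gene does not show where in the gene the reads lie, so it cannot tell a transcript with a deleted part from an intact one. The groups are therefore called the libraries labelled Otud1-/- and the wild-type libraries, and each direction below rests on those labels, which Otud1 itself did not bear out. Of the 15 measured OTU family deubiquitinases, Otud1 had the smallest p; Otud6b averaged 982 ± 52.3 against 1086 ± 53.9 and Tnfaip3, which encodes the A20 protein, 1899 ± 340 against 2613 ± 1022 (SD, n = 3).

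No gene passed the threshold in limma among the 21796 tested, where the lowest adjusted p was 0.179. At an unadjusted p under 0.05, 717 genes were higher and 702 lower in the libraries labelled Otud1-/-. Other splits of the 6 libraries gave between 343 and 2260 such genes, against 1419 in the real split. The groups did not overlap for 11.8% of genes, where chance gives 10%. On the recovered reads, edgeR called 0 genes, with 569 higher and 580 lower at an unadjusted p under 0.05, and DESeq2 called 53 higher and 133 lower. Leaving out 1 library moved the DESeq2 counts to between 33 and 134 higher (134 without wild type replicate 3) and between 41 and 208 lower (41 without wild type replicate 2, 208 without Otud1-/- replicate 1). Without Otud1-/- replicate 1, limma called 47 genes lower and 1 higher.

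Under the naming rule, which leaves out predicted names, 5 genes with higher means in the libraries labelled Otud1-/- are named, none past the threshold in limma. DESeq2 called all 5 higher, with adjusted p from 1.22e-08 (Serpine2) to 0.000254 (Crip2). Serpine2 (chromosome 1, 79794197 to 79861180), a secreted inhibitor of serine proteases, averaged 867 ± 51.5 against 354 ± 67.5 normalised reads in wild type (log2 difference 1.31, SE 0.15, limma adjusted p = 0.179). Wnt5a (chromosome 14, 28504750 to 28527448), a ligand of beta-catenin-independent Wnt signalling, averaged 1169 ± 138 against 642 ± 37. Col18a1, the collagen from which endostatin is cleaved, averaged 2538 ± 163 against 1543 ± 153. Igfbp5, an insulin-like growth factor binding protein, averaged 5034 ± 441 against 3143 ± 139, and Crip2, a LIM-domain protein, 959 ± 82.3 against 575 ± 61.1. For Serpine2, Wnt5a, Col18a1, Igfbp5 and Crip2, each library labelled Otud1-/- lay above each wild-type library, which the naming rule required.

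The 5 genes named by the same rule among those with lower means include 3 interferon-inducible GTPases, again none past the threshold in limma. DESeq2 called all 5 lower, with adjusted p from 6.89e-08 (Gbp3) to 3.2e-05 (Slc39a8). Gbp3 (chromosome 3, 142560026 to 142573209), a guanylate-binding protein, averaged 606 ± 37.1 in the libraries labelled Otud1-/- and 1447 ± 308 in wild type (log2 difference -1.23, SE 0.15, limma adjusted p = 0.179). The immunity-related GTPases Igtp and Irgm1 averaged 1000 ± 158 against 2182 ± 305 and 1571 ± 176 against 3107 ± 485. Btla, an inhibitory receptor of B and T lymphocytes, averaged 42.8 ± 8.95 against 151 ± 28.4, and the metal ion transporter Slc39a8 793 ± 102 against 1390 ± 62.5. Without Otud1-/- replicate 1, limma adjusted p was 0.0495 for Serpine2 and Gbp3, 0.0476 for Igtp and Btla and 0.0495 for Irgm1.

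**Figure D1:**
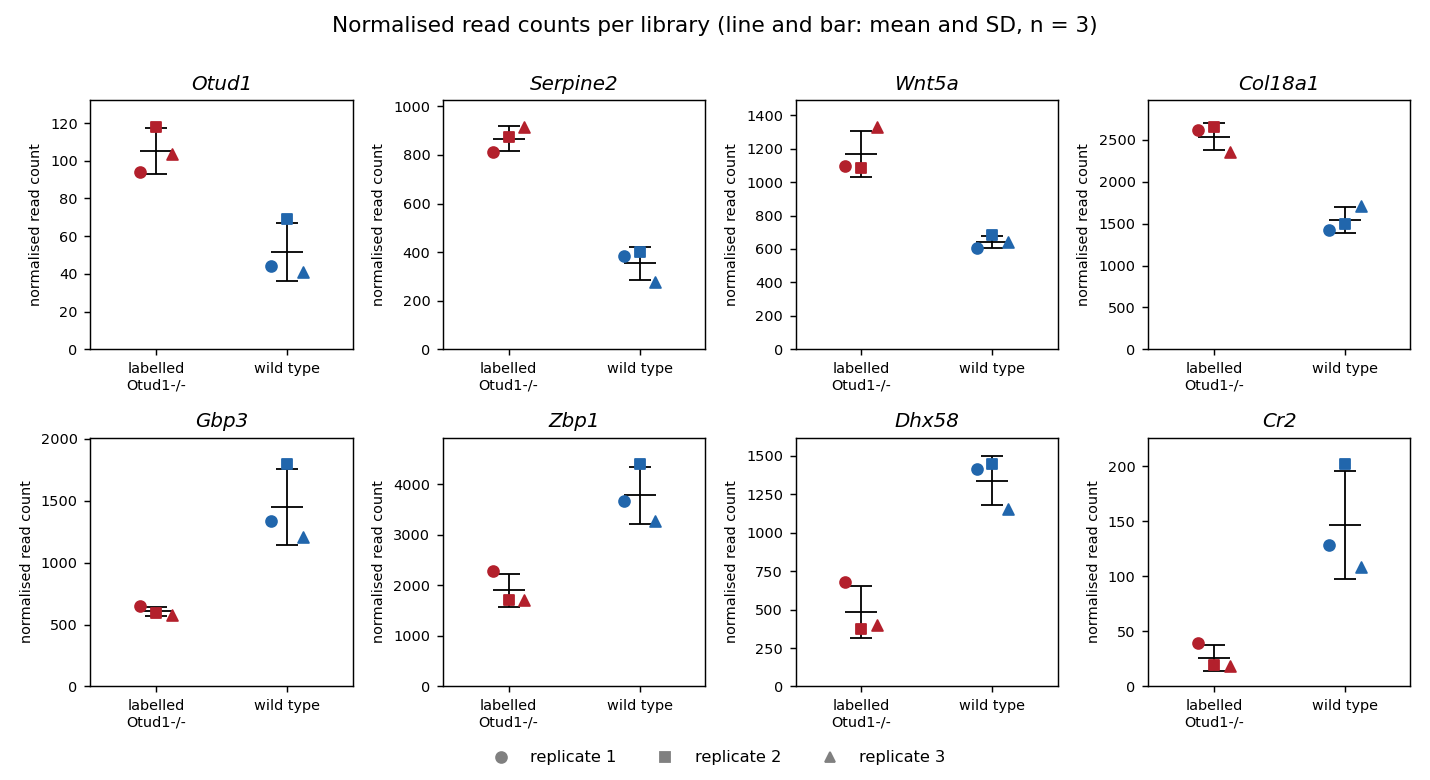
Normalised read counts (y axis, linear from 0) of 8 genes in the 3 libraries labelled Otud1-/- and the 3 wild-type libraries (x axis); points are libraries, the horizontal line and bars are the mean and SD. Otud1 was higher in the libraries labelled Otud1-/- (105 against 51.5), while Gbp3, Zbp1, Dhx58 and Cr2 were lower, and the groups do not overlap for any of the 8. Non-overlap was a condition for naming Serpine2, Wnt5a, Col18a1 and Gbp3.

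Type I interferon-stimulated genes were lower as a group in the libraries labelled Otud1-/-. All 32 measured members had a lower mean, with a median log2 difference of -1.31 and a range of -2.15 to -0.58, and the groups did not overlap for 31 of them. The members included the nucleic acid sensors Zbp1 (1899 ± 335 against 3782 ± 567, SD, n = 3) and Dhx58 (483 ± 168 against 1338 ± 158), and the transcription factor Irf9 (1667 ± 159 against 2615 ± 205). Counted one by one, 0 of 32 passed over all genes in limma, 32 of 32 passed when adjusted over the list alone, and DESeq2 called 26. Without Otud1-/- replicate 1, limma called 13 members lower over all genes. Camera called the list (adjusted p = 1.56e-46), but not with an estimated correlation (adjusted p = 0.348 with an estimated correlation), the estimate being 0.65. Several members of the Ifit, Oas and Mx families have close copies whose reads the counting could split, so their single values are uncertain.

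The interferon-gamma and antigen presentation list was also lower by camera (adjusted p = 2.25e-22; adjusted p = 0.348 with an estimated correlation). Its 32 measured members had lower means, with a median of -0.59, and the groups did not overlap for 18. Apart from Gbp3, Igtp and Irgm1, the member with the smallest p was Tap1, a subunit of the peptide transporter for MHC class I, at 1502 ± 249 against 3082 ± 397. In this list 0 of 32 passed over all genes in limma, 11 of 32 passed when adjusted over the list alone, and DESeq2 called 10. Without Otud1-/- replicate 1, limma called 5 of its members lower over all genes.

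B cell markers were lower in parallel (camera adjusted p = 1.43e-21; adjusted p = 0.348 with an estimated correlation). Of 20 measured members, 19 had a lower mean and 1 a higher one, with a median log2 difference of -1.7. The complement receptor Cr2 averaged 26.1 ± 11.9 in the libraries labelled Otud1-/- and 146 ± 49 in wild type, and Cxcr5, the chemokine receptor that guides cells into follicles, 23.1 ± 12.1 against 119 ± 46.1. Bank1 averaged 33.3 ± 13.8 against 114 ± 31.2, and the IgM receptor Fcmr 22.7 ± 8.27 against 117 ± 61.2. Over all genes 0 of 20 passed in limma, 17 of 20 passed when adjusted over the list alone, and DESeq2 called 10. Without Otud1-/- replicate 1, limma called 5 B cell members lower, and 23 of its 47 lower calls lay in the 2 interferon lists or the B cell list. Otud1-/- replicate 1 lay closest to wild type for the means of both this list and the type I interferon list, at -0.07 and -0.13 log2 units from the mean of the 6 libraries, against -1 and -1.02 in replicate 2 and -1.3 and -0.82 in replicate 3. Of the 133 genes that DESeq2 called lower, 46 belong to the 2 interferon lists or the B cell list; with 1 library left out these were between 25 (of 41, without wild type replicate 2) and 57 (of 208, without Otud1-/- replicate 1).

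T cell markers had a median of 0.04, with 13 of 24 members higher and 11 lower, and the list was not called (camera adjusted p = 0.905). Its result hung on single libraries: it was lower without Otud1-/- replicate 1 (median -0.33, adjusted p = 0.0132) and higher without Otud1-/- replicate 3 (0.23, 0.0333) or wild type replicate 3 (0.35, 0.00794). Within the libraries labelled Otud1-/-, the T cell mean was highest in replicate 1 and lowest in replicate 3 (0.69, -0.13 and -0.54), as was the B cell mean. Cytotoxic and NK cell markers were not called (median 0.1, adjusted p = 0.652) but were lower without Otud1-/- replicate 1 (median -0.45, adjusted p = 0.0134). Dendritic cell markers were not called (adjusted p = 0.534). Plasma cell markers were lower by camera (adjusted p = 0.0026; adjusted p = 0.592 with an estimated correlation), with a median of -0.46 that became -0.04 and lost its call without Otud1-/- replicate 3 (adjusted p = 0.389); it was -0.86 without Otud1-/- replicate 1, -0.73 without Otud1-/- replicate 2 and -0.25 without wild type replicate 1. Ighm, the IgM heavy chain, averaged 452 ± 312 against 1163 ± 116 and Pou2af1, a B lineage coactivator, 201 ± 111 against 419 ± 117, while Prdm1, a regulator of plasma cell differentiation, averaged 539 ± 108 against 395 ± 46.3. In the plasma cell list, 0 of 17 members passed in limma over all genes and 0 when adjusted over the list alone, while DESeq2 called 1 lower. Without Otud1-/- replicate 1, limma called Ighm lower (adjusted p = 0.028).

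Neutrophil markers were lower by camera in the libraries labelled Otud1-/- (adjusted p = 0.000144; adjusted p = 0.348 with an estimated correlation), with 17 of 22 members lower, 5 higher and a median of -0.39. The calprotectin subunit S100a9 averaged 738 ± 223 against 1374 ± 64.1, and Acod1, which makes itaconate, 131 ± 5.36 against 366 ± 218. For these markers 0 passed over all genes in limma, 4 of 22 passed when adjusted over the list alone, and DESeq2 called 4 lower. The median was -0.24 without Otud1-/- replicate 2 and -0.26 without Otud1-/- replicate 3. The IL-17 and IL-22 antimicrobial list, which shares 2 genes with the neutrophil list, was lower (adjusted p = 0.000321; adjusted p = 0.499 with an estimated correlation) with 19 of 24 members lower and 5 higher, and S100a8 at 660 ± 285 against 1518 ± 596. In limma it had 1 member past the threshold when adjusted over the list alone and 0 over all genes, while DESeq2 called 2 lower. Its median of -0.34 became -0.22 without wild type replicate 2.

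Several inflammatory lists were called lower only while wild type replicate 2 was included. NF-kB targets had 24 of 28 members lower, 4 higher and a median of -0.25 (camera adjusted p = 8.75e-05; adjusted p = 0.592 with an estimated correlation), which became -0.09 without that library (adjusted p = 0.289) and -0.42 without wild type replicate 1. Nfkbia averaged 1890 ± 214 against 2712 ± 749. Inflammatory cytokines and chemokines had 26 of 38 members lower, 12 higher and a median of -0.31 (adjusted p = 0.0034; adjusted p = 0.677 with an estimated correlation), which became -0.01 without wild type replicate 2 (adjusted p = 0.733) and -0.58 without wild type replicate 1. Cxcl13, the ligand of the Cxcr5 receptor, averaged 151 ± 93 against 430 ± 76.7, and the interferon-inducible chemokine Cxcl10 189 ± 19.8 against 702 ± 560. STAT3 targets had 13 of 18 members lower and 5 higher (median -0.22, adjusted p = 0.0045; adjusted p = 0.592 with an estimated correlation), with Pim3 at 1081 ± 32.7 against 1489 ± 194. Their median became -0.04 without wild type replicate 2 (adjusted p = 0.156) and -0.13 without Otud1-/- replicate 2 (adjusted p = 0.0508). RIPK1 and TNF receptor signalling had 23 of 27 members lower and 4 higher with a median of only -0.08 (adjusted p = 0.000841; adjusted p = 0.592 with an estimated correlation), which became -0.02 without wild type replicate 2 (adjusted p = 0.0906), -0.04 without Otud1-/- replicate 3 and -0.12 without wild type replicate 3. Its member Mlkl, the effector of necroptosis, averaged 671 ± 68.1 against 1055 ± 135. In limma, no member of these 4 lists passed over all genes, and adjusted over the list alone 0 NF-kB, 0 cytokine, 2 STAT3 and 2 RIPK1 members did. DESeq2 called 0 NF-kB, 2 cytokine, 0 STAT3 and 2 RIPK1 members lower.

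Endothelial and fibroblast lists were higher in the libraries labelled Otud1-/-, while the smooth muscle, enteric neuron and glia, and interstitial cell of Cajal lists were not called. Endothelial markers had 19 of 21 members higher and 2 lower, with a median log2 difference of 0.43 (camera adjusted p = 1.19e-10; adjusted p = 0.477 with an estimated correlation). Egfl7 averaged 441 ± 12.3 against 264 ± 58, the TGF-beta co-receptor Eng 716 ± 25.7 against 534 ± 56.7, and Plvap 931 ± 101 against 676 ± 107. Fibroblast and matrix genes had 23 of 30 members higher and 7 lower, with a median of 0.37 (adjusted p = 1.48e-07; adjusted p = 0.352 with an estimated correlation). Pdgfrb averaged 812 ± 46.7 against 533 ± 51.7, the gelatinase Mmp2 1297 ± 67.9 against 927 ± 49.2, and Col6a3 1502 ± 290 against 876 ± 170. The means of both lists overlapped between the groups. Endothelial stood at 0.11 in wild type replicate 3 and 0.1 in Otud1-/- replicate 1, and fibroblast at 0.12 in wild type replicate 2 and 0.05 in Otud1-/- replicate 3. In limma, no member of either list passed over all genes, and 2 of 21 and 10 of 30 passed when adjusted over the list alone. DESeq2 called 1 endothelial and 3 fibroblast members higher.

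Lists of signalling targets that are active in stroma and epithelium were higher by smaller amounts. YAP targets had 19 of 25 members higher and 6 lower (median 0.26, camera adjusted p = 3.94e-05; adjusted p = 0.348 with an estimated correlation), led by Clu, a marker of regenerating intestinal epithelium, at 11668 ± 612 against 7303 ± 1002, and the receptor kinase Axl at 1176 ± 59.2 against 931 ± 48.2. TGF-beta response genes had 21 of 25 members higher and 4 lower (median 0.13, adjusted p = 0.000133; adjusted p = 0.352 with an estimated correlation), among them Cdkn2b at 889 ± 184 against 607 ± 118. EMT regulators had 11 of 14 higher and 3 lower (median 0.28, adjusted p = 0.0029; adjusted p = 0.348 with an estimated correlation), with the transcription factor Snai2 at 117 ± 15.9 against 47.6 ± 8.43. Markers of endothelium and fibroblasts were higher in the same libraries. p53 targets had 20 of 27 higher and 7 lower (median 0.2, adjusted p = 0.000144; adjusted p = 0.477 with an estimated correlation), with Plk2 at 1427 ± 85.2 against 1038 ± 131; the median was 0.12 without Otud1-/- replicate 1 and 0.13 without wild type replicate 2. NRF2 targets had 21 of 26 higher and 5 lower (median 0.11, adjusted p = 0.0025; adjusted p = 0.478 with an estimated correlation), with the cystine transporter Slc7a11 at 869 ± 125 against 573 ± 137; the median was 0.07 without Otud1-/- replicate 1. In limma, no member of these 5 lists passed over all genes, and adjusted over the list alone 1 YAP and 1 EMT member did. DESeq2 called 1 YAP and 1 EMT member higher.

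**Figure D2:**
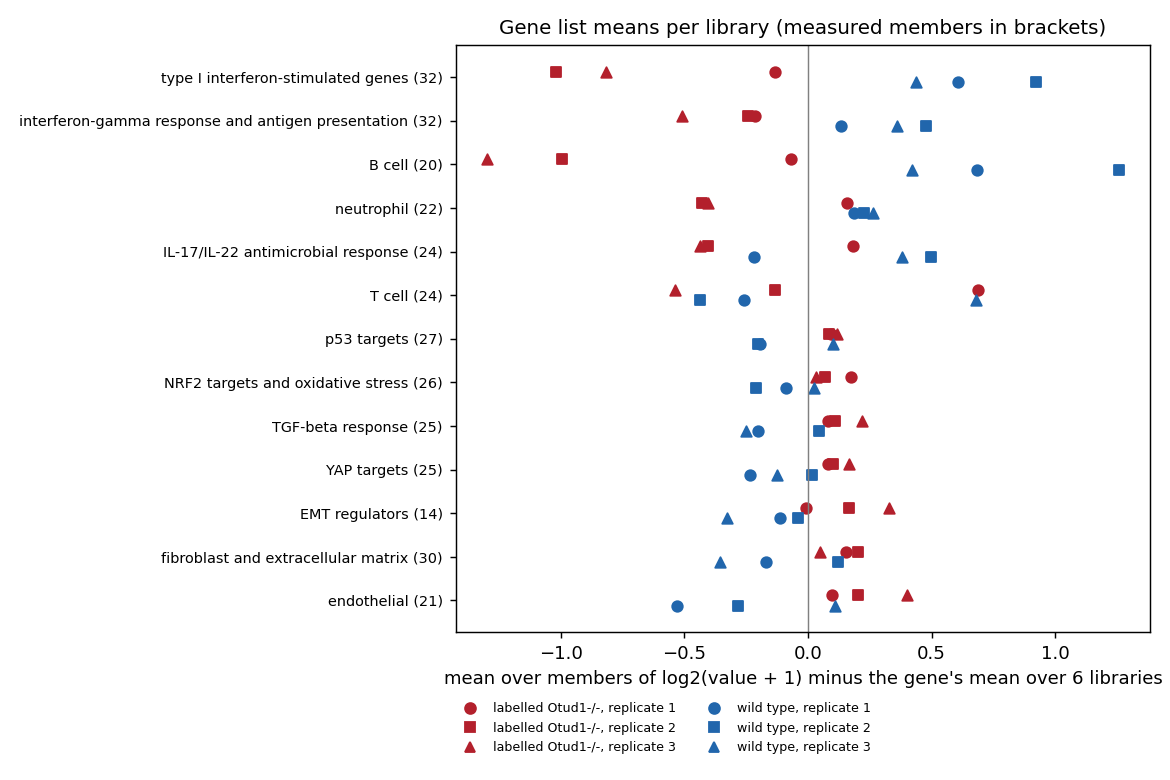
Mean per library (x axis, log2 units, members' deviation from their mean over the 6 libraries) of 13 gene lists (y axis, measured members in brackets); each point is 1 library, coloured by the group of its label. The type I interferon means lie between -1.02 and -0.13 in the libraries labelled Otud1-/- and between 0.44 and 0.92 in wild type. The means of the groups overlap for the T cell, IL-17 and IL-22, p53, fibroblast and endothelial lists.

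Proliferation genes were slightly lower, with 31 of 33 members lower, 2 higher and a median of -0.13 (camera adjusted p = 3.94e-05; adjusted p = 0.592 with an estimated correlation). Foxm1, a regulator of mitotic genes, averaged 657 ± 55.2 against 805 ± 105. The median was -0.05 and the call was lost without Otud1-/- replicate 2 (adjusted p = 0.0841), and it was -0.21 without Otud1-/- replicate 3. Fatty acid oxidation and PPAR targets had 18 of 22 members lower and 4 higher (median -0.17, adjusted p = 0.000474; adjusted p = 0.591 with an estimated correlation), with Acadl at 3751 ± 418 against 5415 ± 837 and the fatty acid transporter Cd36 at 54.1 ± 15.5 against 105 ± 28.6. Their median was -0.07 without wild type replicate 1, which ended the call (adjusted p = 0.11), and -0.1 without Otud1-/- replicate 3. Genes of the unfolded protein response had 18 of 24 lower and 6 higher (median -0.08, adjusted p = 0.0041; adjusted p = 0.592 with an estimated correlation), with Herpud1 at 2569 ± 313 against 3464 ± 51.1. That call was lost without Otud1-/- replicate 3 (median -0.03, adjusted p = 0.0798) and without wild type replicate 3 (median -0.06, adjusted p = 0.0962). In these 3 lists no member passed, over all genes or when adjusted over the list alone.

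The 4 remaining calls each rested on single libraries. Macrophage markers had 22 of 26 members lower and 4 higher (median -0.21, camera adjusted p = 0.0031; adjusted p = 0.677 with an estimated correlation), led by the IgG receptor Fcgr1 at 106 ± 21.5 against 167 ± 41.2. Without Otud1-/- replicate 3 the macrophage median was 0.01 (adjusted p = 0.923), without wild type replicate 3 it was -0.11 (adjusted p = 0.262), and without Otud1-/- replicate 1 it was -0.36. Mast cell markers had 12 of 15 higher and 3 lower (median 0.92, adjusted p = 0.0057; adjusted p = 0.677 with an estimated correlation), and the call was lost without Otud1-/- replicate 1 (median 0.33, adjusted p = 0.455), in which the tryptase gene Tpsab1 stood at 154 against 39.9 and 32.7 in the other libraries with that label, and without wild type replicate 2 (median 0.31, adjusted p = 0.506). The mast cell median stood at 1.79 without wild type replicate 3 and at 0.58 by DESeq2. Immediate early and heat shock genes, listed as a sign of RNA quality and tissue handling, had 19 of 23 higher and 4 lower (median 0.12, adjusted p = 0.0073; adjusted p = 0.596 with an estimated correlation), with Fosb at 3052 ± 592 against 1910 ± 627. The call was lost without Otud1-/- replicate 1 (adjusted p = 0.0879), without Otud1-/- replicate 3 (adjusted p = 0.105) and without wild type replicate 1 (median 0.04, adjusted p = 0.302), and the median was 0.2 without Otud1-/- replicate 2. Goblet cell markers had 18 of 20 lower and 2 higher (median -0.21, adjusted p = 0.0321; adjusted p = 0.827 with an estimated correlation). Their call was lost without wild type replicate 1 (median -0.08), without wild type replicate 2 (median -0.19) and by DESeq2 (adjusted p = 0.0586), their direction turned without Otud1-/- replicate 3 (median 0.1, adjusted p = 0.264), and the median was -0.46 without Otud1-/- replicate 2 and -0.41 without wild type replicate 3. The goblet cell regulator Spdef averaged 655 ± 215 against 802 ± 25.6. No member of these 4 lists passed, over all genes or when adjusted over the list alone.

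The other 22 lists were not called with all libraries, and several of them were called under alternatives. Epithelial lists were among them: Wnt and beta-catenin targets (median 0.07, camera adjusted p = 0.275), absorptive colonocyte (0.08, 0.188), enteroendocrine (-0.21, 0.188), tuft (0.18, 0.534), pan-epithelial (0.07, 0.405) and squamous epithelium (0.19, 0.0539). Squamous epithelium was called higher in 10 of 19 alternatives, among them the stricter filter (adjusted p = 0.00282), edgeR (0.00101), DESeq2 (0.0206) and voom (0.00355), and without wild type replicate 2 (median 0.47, adjusted p = 0.000238). Wnt targets were called higher without Otud1-/- replicate 1 (adjusted p = 0.0372), Otud1-/- replicate 2 (0.0216) or wild type replicate 3 (median 0.2, adjusted p = 0.000565), with medians down to -0.12 without Otud1-/- replicate 3. Absorptive colonocyte genes were called higher without Otud1-/- replicate 3 (median 0.24, adjusted p = 0.00239) or wild type replicate 1 (0.22, 9.55e-05). Enteroendocrine genes were called lower without Otud1-/- replicate 2 (median -0.33, adjusted p = 0.00193) or wild type replicate 3 (-0.51, 0.00101), and pan-epithelial genes higher without Otud1-/- replicate 3 (adjusted p = 0.0461). The Wnt target Ephb3 averaged 1511 ± 74.7 against 1268 ± 110 and Ccnd1, which encodes cyclin D1, 2737 ± 111 against 2435 ± 188. Smooth muscle (median -0.1, adjusted p = 0.336), enteric neuron and glia (-0.01, 0.645), interstitial cell of Cajal (0.07, 0.188), adipocyte (0.06, 0.997), erythroid (0.21, 0.706), and hypoxia and glycolysis (-0.04, 0.507) were not called, nor was the OTU family list (-0.01, 0.837). Smooth muscle went both ways with 1 library left out, and hypoxia and glycolysis was lower without Otud1-/- replicate 1 (median -0.11, adjusted p = 0.0132). Lists of other tissues gave adjusted p of 0.664 for small intestine, 0.837 for skeletal muscle, 0.905 for pancreas and liver, and 0.197 for male accessory gland, which was higher without Otud1-/- replicate 2 (adjusted p = 0.0364). Of the 3 RNA quality lists, immediate early and heat shock was called higher, as described above, and the others gave 0.0834 for mitochondrial transcripts and 0.193 for ribosomal proteins. Mitochondrial transcripts were called higher in 5 alternatives, among them DESeq2 (median 0.14, adjusted p = 0.0339), and ribosomal proteins in 4, among them without Otud1-/- replicate 1 (median 0.08, adjusted p = 0.000226), so a difference in RNA quality between the groups is not excluded. The median, the mean and the camera direction differed in sign for the dendritic cell, cytotoxic and NK cell, enteric neuron and glia, small intestine, OTU family, pancreas and liver, and adipocyte lists.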

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

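The count tests on recovered reads, and DESeq2 with each library left out, were chosen after the data were seen; the other alternatives were fixed before. Without trend and robust fitting, limma called 2 genes higher (Gm16867, adjusted p = 0.00233, and Gm37733, 0.0439) and 1 lower (Gm45206, 0.0439). With 1 library left out it called between 0 and 1 higher and between 0 and 47 lower. The 47 came without Otud1-/- replicate 1, and the cause was not tested. DESeq2 called 53 higher and 133 lower, and 33 to 134 higher and 41 to 208 lower with 1 library left out. In simulated data it made 56 false calls of 234, and the cause of the difference was not tested. Quantile normalization, other filters, other pseudocounts, sample weights, the fold-change threshold, voom and the 3 edgeR scalings each called 0 genes. With the replicate block (the replicate number), limma called 0 genes (lowest adjusted p = 0.0526) and camera 13 lists higher and 15 lower, the added ones being absorptive colonocyte (adjusted p = 0.0177), squamous epithelium (0.034), male accessory gland (0.0327) and mitochondrial transcripts (0.0478); deviations of same-numbered libraries from their group means correlated at -0.02, 0.06 and 0.1, and not every library correlated best with its own number, so the samples share only a number. Otud1 kept its direction and stayed short of the threshold under each alternative, at 0.9 to 1.27 log2 units. Camera with an estimated correlation and fry called 0 lists higher and 0 lower, against 9 and 15 with the preset correlation. For camera, only the correlation setting was changed. The preset was 0.01, while the estimates for the called lists ran from -0.04 (EMT regulators) to 0.74 (mast cell), with 0.65 for type I interferon and 0.68 for B cell. A larger correlation alone does not account for the lost calls. The EMT estimate lay below the preset, yet the unadjusted camera p of that list rose from 0.00108 to 0.0254. What else the setting changes within camera was not tested. Why fry called none was not tested. Of the 24 list calls, 12 held with each library left out. The goblet cell median, between -0.456 and 0.098 with 1 library left out, turned direction without Otud1-/- replicate 3. The T cell median ran from -0.33 to 0.35 and was called lower without Otud1-/- replicate 1 and higher without Otud1-/- replicate 3 or wild type replicate 3. The smooth muscle median ran from -0.23 to 0.071 and was called higher without Otud1-/- replicate 1 and lower without Otud1-/- replicate 2 (adjusted p = 0.0214), Otud1-/- replicate 3 (0.0473) or wild type replicate 3 (0.0365). Of the 95 genes followed under the alternatives, Slc25a37 alone changed direction, in 2 of its values (range -0.046 to 0.17 log2 units, lowest without Otud1-/- replicate 1 and highest without wild type replicate 3). Of 1785 values, 49 passed the threshold, 13 of them outside DESeq2. The largest shift of the median gene under any scaling was 0.011 log2 units. At 14826643 to 23827281 reads, low genes such as Otud1 rest on 31 to 136 reads per library.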

Other observations

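In these paragraphs, the tests on B cells, immune cells, gene copies, Otud1, Gm16867 and Gm21451 were chosen after the values had been seen; the counts over other splits of the libraries were chosen before.

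Some genes stood out within lists that were not called. Each was named by the rule or, where said, after its values were seen, and none passed the threshold in limma. DESeq2 called Krt15 (adjusted p = 0.00207) and Krt4 (0.00976) higher and Itln1 (0.00211) lower, and no other gene of this paragraph. Among absorptive colonocyte genes, the cytochrome P450 gene Cyp2c55 stood at 536, 519 and 499 normalised reads in the libraries labelled Otud1-/- and at 272, 96.4 and 25.2 in wild type. The carbonic anhydrase Car1 averaged 6432 ± 4112 against 2419 ± 564, while Scnn1g, a subunit of the epithelial sodium channel, averaged 47.3 ± 16.2 against 110 ± 45.2. The squamous keratins Krt15 (222 ± 75.5 against 90.7 ± 2.45) and Krt4 (143 ± 76.9 against 38.4 ± 20.2) had higher means in the libraries labelled Otud1-/-. Of small intestinal genes, the lectin Itln1 (1173 ± 96.3 against 2156 ± 505) and the lysozyme Lyz1 (8740 ± 2274 against 15336 ± 5568) had lower means, and the retinol-binding protein Rbp2 (146 ± 12.8 against 88.8 ± 10.4) a higher one. Lyz1 has a close copy, so its value is uncertain. Within the cytotoxic list, the T-box factor Eomes averaged 26 ± 2.73 against 11.1 ± 3.55, and the NK cell receptor genes Ncr1 (0.9 ± 0.04 against 6.23 ± 3.03) and Klrb1c (1.82 ± 0.98 against 6.34 ± 1.49) had lower means, all at few reads. Tuft cell genes also went both ways, with the cation channel Trpm5 at 52.6 ± 7.47 against 32.3 ± 1.83 and Plcg2 at 483 ± 54.6 against 664 ± 18.1. Nnt, a mitochondrial transhydrogenase gene looked at after its values were seen, stood at 15.1 normalised reads or fewer in each library.

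Interferon-stimulated genes were lower together in the libraries labelled Otud1-/-. Reads shared between close gene copies cannot account for all of this. The 18 type I members outside the Ifit, Oas, Mx, Ifi27, Ifi44 and Trim30 families had a median of -0.97, none above -0.58. All 32 measured members were already known to be lower, so that these 18 were lower was fixed in advance. Their values give only the size of the difference outside those families. An equally lower share of immune cells of every type is argued against too, though not an unequal one. The T cell mean minus the B cell mean was 1.59 log2 units higher in the libraries labelled Otud1-/-, without overlap. This repeats the B cell result, as the mean log2 difference was -1.58 for the B cell list and 0.01 for the T cell list. It holds no interferon value. That comparison also rests on the T cell list, whose result hung on single libraries, while the plasma cell, macrophage and neutrophil lists were called lower. A lower share of B cells, as with fewer lymphoid follicles in the piece taken, stays open. Within groups the B cell and interferon means correlated over the 6 libraries (1 relation computed, Pearson r = 0.92, exact one-sided permutation p = 0.0833, Spearman rho = 0.77, exact one-sided permutation p = 0.111). The smallest p of the 36 rearrangements is 0.0278. Without the 2 libraries farthest from the median, Otud1-/- replicate 1 and wild type replicate 2, r was 0.11. The deviations were still taken from group means that included those libraries, so this r is not a within-group correlation of the libraries kept. The genotype itself also stays open, and which group carries it rests on labels that Otud1 did not bear out.

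Otud1 was higher in the libraries labelled Otud1-/-. Exchanged labels with an allele that removes the transcript are argued against, since the lowest Otud1 count of any library was 31 reads. A shift of the whole region is argued against too: the other 11 genes within 1 Mb of Otud1 had a median log2 difference of 0.024 (SD 0.33), and 0 of them had an unadjusted p under 0.05. An allele that leaves part or all of the transcript, with the labels in place or exchanged, cannot be told apart from gene-level values. These differed by 1.05 log2 units, and reads along the gene were not analysed here.

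Gm16867, a predicted gene on chromosome 14 (69363504 to 69503362, minus strand), had 15, 20 and 17 reads in the libraries labelled Otud1-/- and 0 in each wild-type library, at least 4.65-fold higher against a floor of 3 reads per wild-type library. It was the single gene with at least 10 reads in each library of one group and 0 in each library of the other. Gm16867 did not pass in the main limma test. It passed in 2 of 16 alternatives, among them limma without trend and robust fitting (adjusted p = 0.00233). Lower depth of the wild-type libraries is argued against, as they hold 45.5% of all reads. The exact binomial p of 1.96e-14 covers counting error only. It was computed for a gene picked for this pattern among 21851, so it was bound to be small and adds nothing to the counts. A difference between the mice in a duplicated stretch of chromosome 14 stays open, as a hypothesis: Gm21451, a pseudogene inside the same stretch that copies Loxl2, had 26, 4 and 8 reads against 0, 1 and 0 (pooled ratio 31.2, 95% counting interval 5.27 to 1265, with 26 of the 38 reads in Otud1-/- replicate 1), with a fitted difference of 2.95 log2 units that ran from 2.25 to 7.5 over the alternatives. This is 1 gene whose reads can be shared with Loxl2 (1134 ± 91.4 against 820 ± 118), and Slc25a37, looked at as a further gene of the duplicated segment, averaged 1097 ± 142 against 1058 ± 152 (log2 difference 0.05, limma adjusted p = 0.983). Such a difference could come with the background of the mice rather than with Otud1.

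With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, so the counts below give only the real value and values of the other splits. Limma called 0 genes in the real split and at most 2 in another, and all 10 splits had as many as the real one. DESeq2 called 186 genes in the real split and up to 368 in another, with 3 of the 10 splits at least as high. The split with 368 set Otud1-/- replicates 1 and 3 and wild type replicate 3 against the rest, which points to structure among the samples that the labels do not name. That split had 2260 genes at an unadjusted p under 0.05 in limma, against 1419 in the real one. The first principal component of log2 expression (26.6% of variance) parted the same libraries. Its values were -16, -51.5 and -35.5 in these and 10.9, 56 and 36 in the rest. Camera with the preset correlation called 24 lists in the real split and between 12 and 24 in the others, with 2 of the 10 splits at least as high. The number of lists called thus does not set the labels apart from other splits. The absolute median of the type I interferon list was 1.31 in the real split and at most 0.88 in another, and 1 split of the 10, the real one, was that high.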
